A study of Mus musculus with 14 samples.

How the data were processed

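The study measured gene expression by RNA-seq in the cerebral cortex of mice of the SW strain that carried Aldh1l1-GFP, a reporter that marks astrocytes with green fluorescent protein, on postnatal day 14. Upper and deep cortical layers were parted by manual dissection. From each, GFP-positive cells (astrocytes), GFP-negative cells (non-astrocytes) and undissociated tissue (bulk tissue) were taken. The 14 libraries fall into 6 groups, with 3 libraries each for upper and deep layer astrocytes, 2 each for upper and deep layer non-astrocytes and 2 each for upper and deep layer bulk tissue. Per the labels' protocols, cells were freed with papain, dead cells were excluded by DAPI and the GFP gate was set by flow sorting. RNA was extracted with Trizol LS and RNeasy columns and amplified with NuGEN's RNA-Seq system V2, a single primer isothermal amplification. This kit does not require a poly(A) tail, so ribosomal, mitochondrial and unspliced RNA can take a share of the reads. Several libraries shared each sequencing lane, and which library ran in which lane was not given in the sources used here, so no lane effect could be tested.

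Groups were read from the sample titles. For the upper layer astrocytes and upper layer non-astrocytes, the characteristics field names bulk tissue instead, against their titles and descriptions. The titles were followed. The labels number the libraries within each group but do not say that these came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

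Per the submitters' processing notes, CASAVA, TopHat2 2.0.11, HTSeq 0.6.1p1 and DESeq2 (no version given) were used with the GRCm38 build. The deposited values are a signal that equals gene counts divided by 1 size factor per library. In every library the values were whole multiples of the value of 1 read, for 100% of values within 1e-06. The median ratio to the geometric mean over 19787 genes with a read in every library was 0.997798 in each of the 14 libraries, which is what median-of-ratios size factors give. Size factors ran from 0.705 to 1.302. The recovered reads in genes ran from 18226457 to 30316765 per library. Values are called normalised read counts below. No share of reads outside genes could be read from the table. Whether the counting used strand was not given in the sources used here, so genes that overlap the exons of another gene are marked as uncertain, as are near-identical copies such as the globin genes. The table listed 32830 genes. By their identifiers, 32007 were matched to GENCODE M21 (GRCm38) for symbols and coordinates, 71 of the other 823 took their symbol from the table, and 6 repeated symbols were kept under their identifiers. Every value column was mapped to a sample by its name.

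The planned test was edgeR's quasi-likelihood test on counts. Because the deposited values are counts already divided by size factors, limma 3.58.1 in R 4.3.3 (with an intensity trend and robust variance moderation) was used as the leading test, on log2(value + 1). The planned edgeR 4.0.16 and DESeq2 1.42.0 tests were run on the recovered reads as alternatives. Over the 6 comparisons, edgeR called 17 genes for upper against deep layer astrocytes, 7 for non-astrocytes, 170 for bulk tissue, 15105 for astrocytes against non-astrocytes, 14638 for astrocytes against bulk tissue and 1 for the difference between the layer differences of astrocytes and non-astrocytes. A gene was kept if its value reached 10 in at least 2 libraries, which left 22575 genes. A single model of the 6 group means was fitted, with 8 residual degrees of freedom, so all groups shared one estimate of the spread. The comparisons between fractions weigh both layers equally. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Errors beside means are standard deviations over libraries.

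Genes named in the text were taken by a rule. Within a comparison, called genes whose libraries did not overlap between the sides and whose mean level reached 2 (log2 of CPM, the counts scaled to each library's total, or 5 for the comparisons between fractions) were ranked by the size of the change. Predicted genes and pseudogenes were passed over. For the astrocyte layers the first 8 per direction among astrocyte-enriched genes and the first 4 among the rest were taken, and elsewhere the first 8 per direction (the first 5 for the difference between layer differences). Up to 4 members with the smallest p were added for each gene list described, and Chrdl1, Il33 and Aldh1l1 were always given. An astrocyte-enriched gene is one called higher in astrocytes than in non-astrocytes. Called genes outside the rule, members that went against their list and sex-linked genes were singled out after their values were seen. A few genes that the rule would name are not reported here.

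A set of 29 gene lists was fixed in advance. It covered markers of astrocytes, neurons, interneurons, microglia, endothelial cells, mural cells, meningeal fibroblasts, ependyma and choroid plexus, oligodendrocyte precursors and neuroblasts. It also covered upper layer neuron genes, deep layer neuron genes, oligodendrocyte and myelin genes, blood genes, cell cycle genes, white matter and fibrous astrocyte genes, reactive astrocyte genes, synapse-regulating factors, transmitter and potassium uptake genes, cholesterol synthesis genes, glycolysis genes, mitochondrially encoded genes, axon guidance genes, immediate early and dissociation stress genes, and the BMP, Hedgehog, Notch and Wnt pathway genes. The last list, Chrdl1 and Il33, holds genes that the study itself picked from samples of this kind. The other 28 were tested with limma's camera, which asks whether a list's members shift relative to all other genes, with a preset correlation of 0.01, and again with a correlation estimated from the data. Some genes stand in more than 1 list. Counts of members adjusted over the list alone are given beside counts adjusted over all genes.

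Astrocyte libraries that carry the same number in both layers deviated from their group means together. Over 13734 genes with a mean value of at least 100, r was 0.31, 0.22 and 0.34 for libraries of the same number and -0.06 to -0.22 for the others. Deviations from a group mean sum to 0, so the values for other numbers are partly forced below 0. The numbers were taken to pair the astrocyte libraries, on the strength of the data and not of a statement in the labels. Same-numbered non-astrocyte libraries had an r of 0.7 and bulk libraries 0.24 over these genes. With only 2 libraries per layer there, the other pairing is the mirror of this (-0.7 and -0.24). Replicate libraries differed by 10.9 to 140 times the sampling noise (chi-square per degree of freedom). Separately amplified repeats of a sample would exceed it too, so this does not show separate animals.

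The test was checked on simulated counts with 200 genes changed by known folds. The changed genes were drawn from those with a mean value of at least 100, so the shares below do not cover genes with lower values. Libraries were simulated as independent, with no pairing and none that stood apart. Each comparison gave 4 to 6 false calls. For the astrocyte layers it recovered 7.5% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 93.9% of those changed 4-fold (22234 genes). For the non-astrocyte layers these shares were 1.5%, 37.3% and 100% (22212 genes), and for the bulk tissue layers 0%, 37.3% and 93.9% (22218 genes). For astrocytes against non-astrocytes 22.4%, 86.6% and 100% were recovered (21720 genes). Alternatives planned before the data were examined were DESeq2, other scaling factors, no filter, a model of only the groups compared, a replicate block, a fold threshold, limma's fry (which tests a list against no change) in place of camera and leaving out each library. Those added afterwards were TMM scaling within limma, pseudocounts of 0.5 and 10, library quality weights, a separate replicate block within each fraction and leaving out 2 libraries that stood apart. Figures were drawn with matplotlib 3.10.9.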

Results

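The data came from the cortex of mice on postnatal day 14 that carried Aldh1l1-GFP, a reporter that makes astrocytes fluoresce green. Upper and deep cortical layers had been parted by dissection. From each, sorted astrocytes, the remaining GFP-negative cells (non-astrocytes) and undissociated bulk tissue were sequenced, in 14 libraries of 18226457 to 30316765 reads in genes. Expression is given as normalised read counts, which are the deposited counts per gene after division by a size factor per library. Differences are log2 ratios from limma, with standard deviations over libraries beside the means.

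Sorted astrocytes were first compared with the non-astrocytes, over both layers (n = 6 against 4), to see what the sort had separated. Gjb6, which encodes the gap junction protein connexin 30, rose to 29300 ± 9700 (SD, n = 6) in astrocytes against 423.3 ± 94.4 (SD, n = 4), a 67.4-fold difference (chromosome 14, 57123303 to 57133611, GRCm38). Cldn10, a claudin, rose from 96.08 ± 9.18 to 6372 ± 1580, and Aldoc, a brain form of the glycolytic enzyme aldolase, from 1251 ± 144 to 72440 ± 10100 (limma adjusted p = 4.52e-14). Bmpr1b, a BMP receptor (log2 5.84), the transcription factor gene Sox1 (log2 5.79), the cytochrome P450 gene Cyp4f15 (log2 5.77), the membrane protein gene Mlc1 (log2 5.76) and the serine protease gene Prss56 (log2 5.73) followed. Aldh1l1 itself, the folate enzyme gene whose regulatory sequence drives the reporter, rose 31.5-fold from 114.9 ± 16.6 to 3694 ± 750, and its exons overlap those of Gm15756. Chrdl1, which encodes a secreted BMP antagonist, rose 42.4-fold from 145.6 ± 65.1 to 6669 ± 3650. Il33, which encodes a nuclear cytokine, rose 14.2-fold from 101.6 ± 25.5 to 1499 ± 551 (adjusted p = 9.81e-11). Chrdl1 and Il33 were picked by the study from samples of this kind, so they are not independent evidence for it.

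Transcripts of the other cell types fell in the astrocyte libraries. The alpha and beta globin genes Hba-a2 (log2 -7.86), Hbb-bt (log2 -7.71), Hbb-bs (log2 -7.54) and Hba-a1 (log2 -7.44) fell furthest along with the peptidase gene Anpep (200-fold lower) and Col3a1, a fibrillar collagen gene (from 3695 ± 1450 to 20.36 ± 15). How reads were shared between the near-identical globin copies is uncertain. Ptprc, the leukocyte marker CD45, fell from 2249 ± 256 to 17.76 ± 15.8, and the secreted glycoprotein gene Vtn from 12620 ± 3100 to 89.62 ± 52.

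By fixed list, each of the 20 astrocyte markers rose (camera adjusted p = 5.25e-16, 0.0799 with an estimated correlation), among them Fgfr3 (28310 ± 3400 against 639.5 ± 70.2) and Ntsr2 (log2 5.52). Each of the 15 microglia markers fell (adjusted p = 1.03e-09, 0.153 with an estimated correlation), such as the fractalkine receptor gene Cx3cr1 (378.1 ± 106 against 29340 ± 4980) and P2ry12 (log2 -6.59, exons overlapping Med12l). Each of the 12 endothelial markers fell (adjusted p = 1.81e-08, 0.0799 with an estimated correlation), such as the VEGF receptor gene Kdr (92.64 ± 31.3 against 7307 ± 2080). The 10 mural cell markers all fell (adjusted p = 1.15e-06, 0.0799 with an estimated correlation), such as Rgs5 (2308 ± 923 against 212700 ± 32400) and the smooth muscle actin gene Acta2 (log2 -6.37), and so did the 10 meningeal fibroblast markers (adjusted p = 5.65e-06, 0.0799 with an estimated correlation), such as Dcn (log2 -6.90). Of the 15 oligodendrocyte and myelin genes 13 fell (adjusted p = 2.75e-05, 0.108 with an estimated correlation), with Mbp at 695.4 ± 347 against 26440 ± 11300, while Aspa (log2 2.78) and Gpr37 (log2 1.08) rose. All 11 oligodendrocyte precursor genes fell (adjusted p = 2.3e-05, 0.153 with an estimated correlation), led by Enpp6 (67.31 ± 24.4 against 8381 ± 2760). All 15 neuron markers fell (adjusted p = 4.26e-07, 0.0799 with an estimated correlation), such as the synaptic vesicle gene Syt1 (47.26 ± 11.5 against 1330 ± 319) and Snap25 (log2 -3.94). The 5 blood genes fell (adjusted p = 0.0068, 0.257 with an estimated correlation), and 10 of the 13 cell cycle genes fell (adjusted p = 0.00758, 0.257 with an estimated correlation), such as Cdk1 (log2 -4.27).

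Lists of cell functions moved as well. All 17 cholesterol synthesis genes rose in astrocytes (adjusted p = 8.88e-10, 0.0799 with an estimated correlation), with Msmo1 at 18920 ± 3440 against 1579 ± 389 and Sqle at log2 2.93. Of the 15 transmitter and potassium uptake genes 14 rose (adjusted p = 2.58e-09, 0.0799 with an estimated correlation), led by the glutamate transporter genes Slc1a2 (844700 ± 156000 against 21280 ± 3340, exons overlapping Gm13872) and Slc1a3 (log2 4.88), and Slc38a1 fell (log2 -5.14). All 18 immediate early and dissociation stress genes fell (adjusted p = 3.58e-08), such as Egr1 (496.5 ± 82.3 against 10550 ± 2010) and Zfp36 (log2 -4.85). Of the 17 glycolysis genes 13 rose (adjusted p = 0.000625, 0.257 with an estimated correlation), such as Pfkp (log2 2.67, exons overlapping Pitrm1), and 2 fell, Hk2 (168.1 ± 18.2 against 1594 ± 370) and Eno2 (log2 -0.91). Of the 7 Hedgehog response genes 5 rose (adjusted p = 0.00573, 0.108 with an estimated correlation), with the transcription factor gene Gli2 at 3585 ± 377 against 130.1 ± 21.7, and Cdon fell (log2 -3.95). Of the 14 synapse-regulating factors 9 rose (adjusted p = 0.00845, 0.255 with an estimated correlation), such as Sparcl1 (log2 3.29) and the engulfment receptor gene Megf10 (log2 5.29), and 4 fell, among them Tgfb1 (log2 -6.29). Of the 20 axon guidance genes 17 fell (adjusted p = 0.000242, 0.095 with an estimated correlation), such as the netrin receptor gene Unc5b (log2 -4.51). Of the 17 reactive astrocyte genes 13 fell (adjusted p = 0.00763, 0.255 with an estimated correlation), such as Vim (227.9 ± 84.8 against 4858 ± 1490), and Gfap (log2 4.61), Serpina3n (log2 3.85), Cd44 (log2 2.33) and Aspg (log2 1.91) rose.

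In this comparison 14978 of 22575 genes were called, 6677 higher and 8301 lower in astrocytes, and 9960 of them differed at least 2-fold. Of the lists called, only the immediate early and dissociation stress genes stayed called with a correlation between genes estimated from the data (adjusted p = 0.00753). Not called were the interneuron markers (adjusted p = 0.117), the upper (0.62) and deep (0.231) layer neuron genes, the ependymal and choroid plexus markers (0.454), the neuroblast genes (0.0627), the white matter and fibrous astrocyte genes (0.34), and the BMP (0.836), Notch (0.101), Wnt (0.422) and mitochondrially encoded (0.251) genes. Among the upper layer neuron genes 5 rose in astrocytes, such as Lhx2 (log2 4.57), Rorb (log2 3.51) and Pou3f2 (log2 3.40). The BMP list had a median log2 difference of -0.675 and a mean of -0.266, while its test pointed up.

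**Figure D1:**
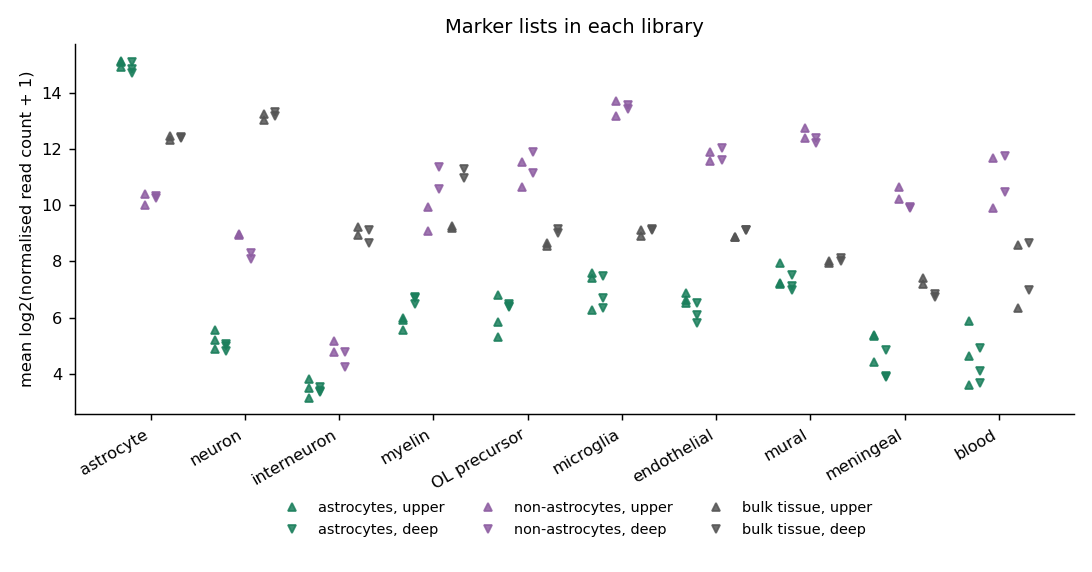
Mean log2(normalised read count + 1) of the members of 10 cell type marker lists (vertical axis) for each of the 14 libraries, with colour for the fraction, upward triangles for upper layers and downward triangles for deep layers, and no error bars. All 20 astrocyte markers were higher in astrocytes than in non-astrocytes, and all 15 neuron markers were lower in astrocytes than in bulk tissue.

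Astrocytes were also compared with bulk tissue (n = 6 against 4), which keeps the cells that dissociation loses. F3, which encodes tissue factor, rose 24.8-fold, from 546.5 ± 45.5 in bulk tissue to 13900 ± 3750 in astrocytes (limma adjusted p = 7.59e-12). The transporter gene Atp13a4 (9891 ± 2170 against 439.1 ± 30), the hypoxia-inducible factor gene Hif3a (9110 ± 2540 against 430.3 ± 79.6), the cytokine gene Il18 (4402 ± 440 against 218.1 ± 34.2), the growth factor receptor gene Egfr (24010 ± 8190 against 1166 ± 191), the innate immune receptor gene Tlr3 (log2 4.34) and the noncoding RNA Celrr (log2 4.41) also rose. The Y-linked gene Eif2s3y rose from 323.2 ± 362 to 2431 ± 346 (log2 4.90, SE 1.325), with bulk libraries at 13 and 615 in the deep layers and 6 and 658 in the upper layers. The sex make-up of the bulk libraries, described below, bears on this difference. Chrdl1 rose 8.07-fold over 776.7 ± 375, Il33 rose 4.11-fold over 357.9 ± 102, and Aldh1l1 rose 4.01-fold over 917.2 ± 184. Among the genes that fell furthest were Slc17a7, the vesicular glutamate transporter of cortical neurons (13.17 ± 8.46 against 16260 ± 2390), the neuropeptide gene Cck (9.226 ± 6.98 against 7795 ± 875), the ubiquitin ligase gene Rnf112 (0.5492 ± 0.901 against 2535 ± 264), the microRNA host gene Mir124a-1hg (log2 -10.06), Ckmt1 (log2 -9.98, exons overlapping Strc), Mal2 (log2 -9.80), Robo3 (log2 -9.78) and Lamp5 (log2 -9.76).

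All 15 neuron markers fell (camera adjusted p = 1.71e-11), with Syt1 at 47.26 ± 11.5 against 25780 ± 2510, and all 14 interneuron markers fell (7.45e-07, 0.0564 with an estimated correlation), with the GABA synthesis enzyme genes Gad1 (log2 -6.00) and Gad2 (log2 -3.74) among them. Of the 20 deep layer neuron genes 17 fell (0.000289), such as Tbr1 (log2 -5.57), and of the 16 upper layer neuron genes 11 fell (0.0199, 0.15 with an estimated correlation), such as Cux2 (71.33 ± 15.4 against 4646 ± 3290). All 20 astrocyte markers rose (1.01e-11, 0.0619 with an estimated correlation), such as the water channel gene Aqp4 (30820 ± 5990 against 1943 ± 154). All 17 cholesterol synthesis genes rose (1.81e-09, 0.0619 with an estimated correlation), such as Msmo1 (log2 3.68). So did 13 of the 15 transmitter and potassium uptake genes (1.79e-06, 0.0892 with an estimated correlation), such as the connexin 43 gene Gja1 (57240 ± 14500 against 3738 ± 238), and 10 of the 14 synapse-regulating factors (8.57e-05, 0.0907 with an estimated correlation), such as the phagocytic receptor gene Mertk (26690 ± 3860 against 2024 ± 49.5). Also higher were 8 of the 9 Notch pathway genes (6.25e-05, 0.0564 with an estimated correlation), such as Notch2 (7815 ± 1200 against 616.9 ± 23.7), and 6 of the 7 Hedgehog response genes (0.00233, 0.0805 with an estimated correlation), such as Hhip (201 ± 154 against 46.52 ± 24.6). Dll1, a Notch ligand gene, fell (log2 -3.17). Of the 15 myelin genes 13 fell (2.54e-05, 0.0907 with an estimated correlation), with Mbp at log2 -5.95. Also lower were 11 of the 12 endothelial markers (2.54e-05, 0.124 with an estimated correlation) and all 15 microglia markers (0.000113, 0.339 with an estimated correlation), such as Cx3cr1 (log2 -2.10). The same was true of 9 of the 11 precursor genes (0.011, 0.35 with an estimated correlation), 8 of the 9 neuroblast genes (0.000332, 0.0564 with an estimated correlation), such as Dcx (log2 -4.52), and 8 of the 10 meningeal fibroblast markers (0.0223, 0.321 with an estimated correlation). Of the 20 axon guidance genes 17 fell (1.89e-05, 0.0574 with an estimated correlation), such as Robo2 (log2 -5.73). Of the 18 immediate early and dissociation stress genes 11 fell (0.00519, 0.0574 with an estimated correlation), such as Arc (log2 -9.14), while Zfp36 (log2 2.05) and Hspa1a (log2 0.91) rose.

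Against bulk tissue 14637 of 22575 genes were called, 6498 higher and 8139 lower in astrocytes, 9691 of them at least 2-fold. Of the lists called, only the neuron markers (adjusted p = 0.0427) and the deep layer neuron genes (0.0427) stayed called with an estimated correlation. Not called were the mural cell markers, ependymal markers, BMP genes and glycolysis genes (adjusted p = 0.439 each), the cell cycle genes (0.447), the blood genes (0.0632), the white matter astrocyte genes (0.0885), the Wnt genes (0.109), the reactive genes (0.928) and the mitochondrially encoded genes (0.695). In the cell cycle list the mean of -0.022 and in the BMP list the median of -0.126 had the opposite sign to the test. The non-astrocyte libraries held few transcripts of the neuron markers beside bulk tissue. The summed normalised read counts of the neuron markers came to 11400 in non-astrocytes and 306600 in bulk tissue, or 3.717% of the bulk level, while the microglia markers came to 284400 and 11980. The sums of the other neuronal lists stood at 63.93% (interneuron markers), 34.88% (upper layer neuron genes) and 32.09% (deep layer neuron genes) of the bulk level. Most of the interneuron sum in non-astrocytes came from 1 member, Maf (7436.8 in the deep and 7126.1 in the upper layers). As means of log2 levels over list members, the neuron markers ran from 8.07 to 8.97 in non-astrocytes and from 13.05 to 13.31 in bulk tissue, and the interneuron markers from 4.23 to 5.15 and from 8.64 to 9.23. The upper layer neuron genes ran from 7.43 to 8.50 and from 9.43 to 11.30, and the deep layer neuron genes from 6.37 to 7.02 and from 7.36 to 9.47.

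The dissection was then examined in bulk tissue, upper against deep layers (n = 2 each), where genes of upper and deep layer neurons serve as markers of each side. Cux2, a transcription factor gene of upper layer neurons, rose to 7480 ± 162 in the upper layers against 1812 ± 511 (limma adjusted p = 0.00201), and its relative Cux1 to 18000 ± 1490 against 5657 ± 654 (adjusted p = 2.53e-04, exons overlapping Gm16599). Stard8 (log2 2.05, adjusted p = 1.37e-04), the protocadherin gene Pcdh20 (log2 1.94), the exchange factor gene Rasgrf2 (log2 1.90), Evc2 (log2 1.84), the adhesion gene Nectin3 (3660 ± 15.9 against 1196 ± 74.2), the potassium channel gene Kcnh5 (log2 1.58) and Pou3f2 (log2 1.07) also rose. Fezf2, a transcription factor gene of neurons that project below the cortex, fell to 78.89 ± 26.6 against 1337 ± 14.8 (log2 -4.11, adjusted p = 0.00278, chromosome 14, 12342094 to 12348189, GRCm38). Crym (11.34 ± 6.12 against 309.5 ± 63.9), the calmodulin-binding protein gene Pcp4 (302.6 ± 6.96 against 4055 ± 193), Foxp2 (57.98 ± 12.9 against 588.6 ± 196), Nr4a2 (log2 -2.73), Bcl11b (log2 -2.66), Tle4 (616.8 ± 15.3 against 2229 ± 316), the collagen gene Col6a1 (log2 -2.95) and the protease gene Adamts16 (26.18 ± 7.28 against 185.5 ± 53.3) fell too.

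Of the 16 upper layer neuron genes 6 rose, and 16 did when adjusted over the list alone (camera adjusted p = 2.05e-32, median log2 1.587). Of the 20 deep layer neuron genes 11 fell, and 15 when adjusted over the list alone (adjusted p = 1.46e-32, median log2 -1.757). Of the 15 oligodendrocyte and myelin genes 6 fell in the upper layers, and 14 when adjusted over the list alone (adjusted p = 1.69e-28, median log2 -1.801), with Mbp at 20780 ± 1570 against 72050 ± 5940 and Ugt8a, a myelin lipid enzyme gene, at log2 -1.69. These 3 lists stayed called with an estimated correlation (adjusted p = 0.000157, 2.76e-05 and 0.00246). The cholesterol synthesis genes shifted down (5.51e-05, 0.415 with an estimated correlation) with 16 of 17 members below 0, and so did the oligodendrocyte precursor genes (0.0157, 0.82 with an estimated correlation). The axon guidance list was not called (adjusted p = 0.26), although 5 of its members rose and 7 fell when adjusted over the list alone. The astrocyte markers were not called (adjusted p = 0.798), with a median of 0.051 and a mean of -0.019. Chrdl1 stood at 1086 ± 196 in the upper layers and 467.3 ± 3.71 in the deep layers (log2 1.20). This passed with edgeR (adjusted p = 0.0451), DESeq2 (0.00356) and limma with a block within fraction (0.0444). It did not pass with limma without a block (0.0646) or with a replicate block shared by all fractions (0.0566). Il33 (281.4 ± 86.5 against 434.4 ± 12.8, adjusted p = 0.646) and Aldh1l1 (log2 -0.43, adjusted p = 0.791) did not pass either.

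In bulk tissue 103 genes were called between the layers, 36 higher and 67 lower in the upper layers, 96 of them at least 2-fold, and 1639 had an unadjusted p under 0.05. In a fit of only the bulk libraries 1093 were called, 564 higher and 529 lower, so the excess of lower calls was not kept over all calls there, though it was among those of at least 2-fold (192 higher and 316 lower). The count of 103 rested on every library, falling to 11 without deep layer replicate 1, 19 without deep layer replicate 2, 20 without upper layer replicate 1 and 15 without upper layer replicate 2. Of the 22 named and called genes, 7 (Adamts16, Cux1, Foxp2, Nectin3, Nr4a2, Stard8 and Tle4) stayed called whichever library was left out. The other 15 lost their call at least once, with adjusted p between 0.0502 and 0.581.

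**Figure D2:**
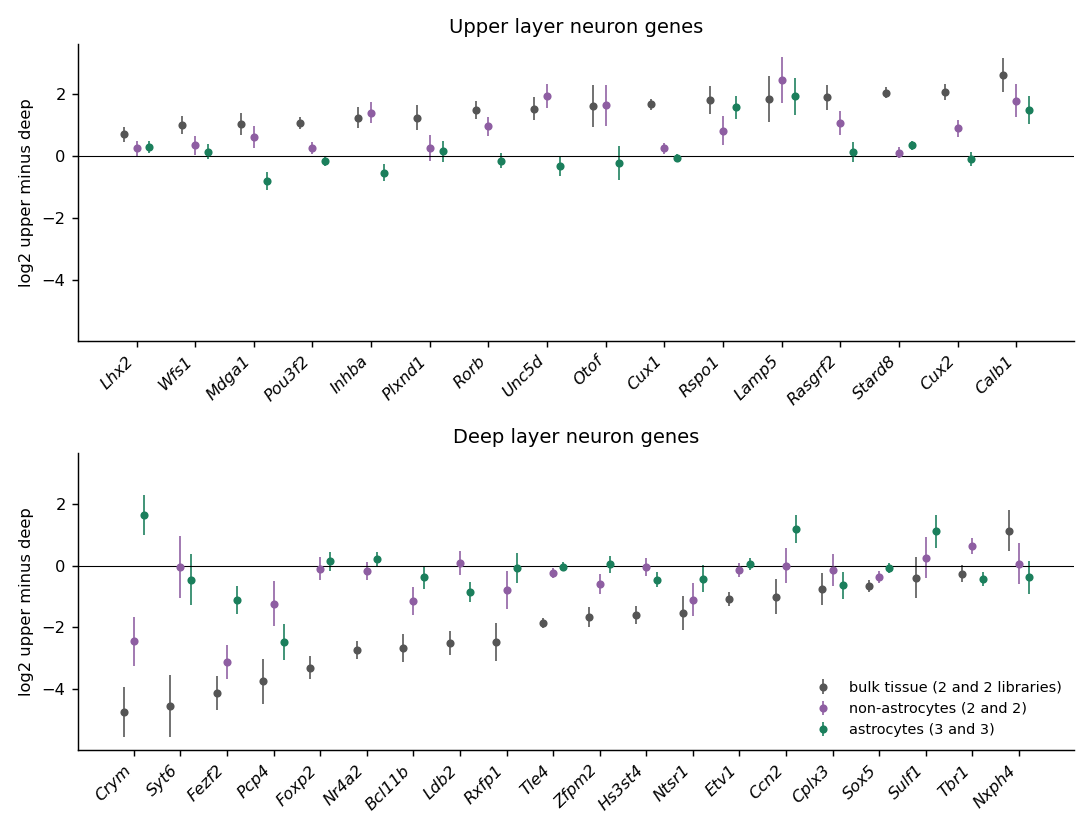
Log2 difference in normalised read count, upper minus deep layers, with standard errors from limma as bars, for each member of the upper (top panel) and deep (bottom panel) layer neuron lists in bulk tissue (grey), non-astrocytes (purple) and astrocytes (green). In bulk tissue the medians were 1.587 for the upper and -1.757 for the deep layer list.

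Among the non-astrocytes, upper against deep layers (n = 2 each), 1 gene was called. Reln, which encodes reelin, the secreted protein of Cajal-Retzius cells and some interneurons, rose to 264.7 ± 2.43 in the upper layers against 62.63 ± 2.74, a 4.18-fold difference (limma adjusted p = 0.00248, SE 0.218). It lies on chromosome 5 from 21884454 to 22344702 (GRCm38, ENSMUSG00000042453), and its exons overlap those of Gm10475. Bulk tissue did not show this rise, with Reln at 1196 and 1346 in the upper layers against 1412 and 1820 in the deep layers (log2 -0.337). Without upper layer non-astrocyte replicate 1 it lost its call (adjusted p = 0.0515), which left 0 calls by limma and 700 genes with an unadjusted p under 0.05, and without deep layer replicate 1 there were 5 calls. In a fit of only the non-astrocytes Reln was not called (adjusted p = 0.508). Over all libraries 871 genes had an unadjusted p under 0.05, and edgeR called 7 genes and DESeq2 139. Chrdl1 stood at 201.6 ± 1.74 against 89.62 ± 13.4 (adjusted p = 0.244), Il33 at log2 0.36 and Aldh1l1 at log2 0.05, none of which passed.

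Lists moved where single genes did not. The 15 oligodendrocyte and myelin genes were all lower in upper layer non-astrocytes (camera adjusted p = 4.59e-25), 11 of them when adjusted over the list alone, with Mbp at 16670 ± 1370 against 36210 ± 411. The 17 cholesterol synthesis genes were all lower (2.61e-21), 10 when adjusted over the list alone, with Hmgcs1 at 1640 ± 146 against 3086 ± 476 and Fdps at 183.9 ± 17.9 against 367.3 ± 9.07. The 16 upper layer neuron genes were all higher (6.43e-16), 7 when adjusted over the list alone, with Unc5d at 563.4 ± 55.5 against 159.7 ± 94.6 and Lamp5 at 241.9 ± 50.1 against 43.63 ± 11.5 (adjusted p = 0.597 with limma and 0.0404 with edgeR). The neuron markers shifted up (3.29e-12), 4 when adjusted over the list alone, with the kinase gene Camk2a at 3383 ± 421 against 1351 ± 577. The deep layer neuron genes shifted down (0.000624), 1 when adjusted over the list alone, with Fezf2 at log2 -3.12. The 18 immediate early and dissociation stress genes were all higher (0.000593), by a median of 0.227. These 6 lists stayed called with an estimated correlation (adjusted p = 0.00537, 0.0143, 0.00447, 0.0143, 0.0162 and 0.0162, in the order given). The calls of the interneuron markers (up, 0.0123, and 0.393 with an estimated correlation), precursor genes (down, 0.0123, and 0.497), mural cell markers (up, 0.0102, and 0.449), meningeal fibroblast markers (up, 0.000655, and 0.228) and mitochondrially encoded genes (down, 0.000139, and 0.497) did not. Upper layer non-astrocyte replicate 1 stood apart from the other libraries, with a read in 30333 genes and a mitochondrial share of 3.04% of reads. Without it and deep layer astrocyte replicate 2, the interneuron (0.709), precursor (0.803) and mitochondrial (0.383) lists were no longer called. By limma, no member of the lists of this paragraph passed when adjusted over all genes.

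Upper layer astrocytes were compared with deep layer astrocytes (n = 3 each), the question the sort was made for. Chrdl1 rose to 9811 ± 1340 in the upper layers against 3527 ± 1350 in the deep layers, a 2.89-fold difference (log2 1.53, SE 0.215, limma adjusted p = 0.0106; ENSMUSG00000031283, chromosome X, 143285674 to 143394262, GRCm38). Inka2, which encodes an inhibitor of the kinase PAK4, rose to 3734 ± 966 against 1311 ± 219 (adjusted p = 0.00279). Eogt, which encodes an enzyme that adds N-acetylglucosamine to EGF repeats such as those of Notch, rose to 29610 ± 953 against 12420 ± 3350 (adjusted p = 0.00727). Tnfrsf19, a receptor gene of the tumour necrosis factor family, rose to 12410 ± 2170 against 6460 ± 227 (log2 0.93, adjusted p = 0.0279). These genes were also enriched in astrocytes over non-astrocytes. A last astrocyte-enriched gene, the desmosome gene Pkp2, had the lowest level among them and rose to 71.3 ± 8.7 against 8.6 ± 5.5 (log2 3.09, adjusted p = 0.0132), so that 5 of 5 called astrocyte-enriched genes were higher in the upper layers. With other settings some were lower, 12 of 50 with DESeq2, 3 of 25 with the replicate block, 10 of 54 with the block within fraction, 3 of 16 without the 2 libraries that stood apart and 2 of 8 when enriched over bulk tissue. In a fit of only the astrocyte libraries none of these genes was called, and Chrdl1 had an adjusted p of 0.286. Enrichment over non-astrocytes does not set a gene apart from neuronal ones, as neuron markers there summed to 3.717% of the bulk level. Inka2 was lower in deep layer astrocytes (1315, 1091 and 1529) than in deep layer bulk tissue (2904 and 2887). In the upper layers it stood at 2990, 3386 and 4826 against 4709 and 5513.

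Among the called genes not enriched in astrocytes over non-astrocytes, Cntnap2, a neuronal cell adhesion gene, rose to 221.3 ± 124 against 30.5 ± 9.66 (adjusted p = 0.00279). Lef1, a transcription factor gene of the Wnt pathway, rose to 2024 ± 248 against 815.2 ± 94.6 (adjusted p = 0.00279), Art3 (exons overlapping Cxcl10) to 748.4 ± 2.97 against 283.4 ± 70.5, and the kinase gene Lyn (exons overlapping Gm26857) to 713 ± 74.4 against 353.2 ± 39.3. Hhip, which encodes a membrane protein that binds and limits Hedgehog ligands, fell to 61.24 ± 12.9 in the upper layers against 340.7 ± 15.8, 5.56-fold lower (adjusted p = 0.00102; ENSMUSG00000064325, chromosome 8, 79965851 to 80058006, GRCm38). Id1, a target gene of BMP signalling, fell to 61.4 ± 6.13 against 194.4 ± 31 (log2 -1.64, adjusted p = 0.00279). Mbp fell to 411.6 ± 108 against 979.2 ± 217 (adjusted p = 0.0163), and the tetraspanin gene Tspan2 (exons overlapping Tspan2os) to 70.5 ± 10.1 against 169.2 ± 31.1. Against bulk tissue of the same layer, Lef1 and Hhip were higher in every astrocyte library, while Cntnap2, Mbp and Tspan2 were lower. Pkp2 and 5 more called genes fell outside the naming rule and were singled out after their values were seen. These were the receptor kinase gene Ror2 (log2 -3.28, adjusted p = 0.0319), the adenylate cyclase gene Adcy8 (17.2 ± 4.2 against 129.5 ± 64.6), Mycn (log2 -2.90), Prune2 (251.4 ± 12.9 against 577.6 ± 114) and the predicted gene Gm12522 (listed at 0 in the upper layers against 4.9 ± 1.5). Il33 stood at 1098 ± 173 in the upper layers against 1899 ± 497 (log2 -0.77, SE 0.24) and did not pass (adjusted p = 0.339), and Aldh1l1 at 4203 ± 373 against 3184 ± 699 did not pass either (adjusted p = 0.467).

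**Figure D3:**
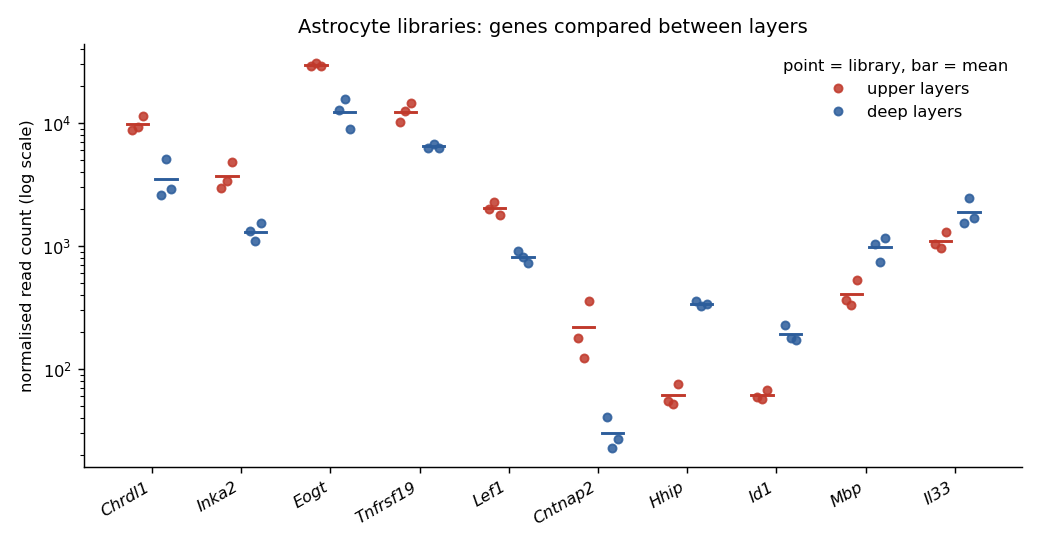
Normalised read count (log axis) of 10 genes in each upper layer (red) and deep layer (blue) astrocyte library, with points for libraries, bars for group means and no error bars. Chrdl1 had means of 9811 and 3527 in upper and deep layers, Hhip 61.24 and 340.7, and Il33, which was not called, 1098 and 1899.

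By fixed list, the oligodendrocyte and myelin genes were lower in upper layer astrocytes (camera adjusted p = 3.23e-07, 0.196 with an estimated correlation, median log2 -0.79). Of 15 members Mbp was called, and 7 passed when adjusted over the list alone, such as Ugt8a (43.77 ± 17.6 against 107.5 ± 19.5). The Wnt response genes were higher (3.52e-06, 0.0946 with an estimated correlation), with 8 of 8 members above 0, Lef1 called and 5 passing when adjusted over the list alone, such as Axin2 (1464 ± 188 against 860.4 ± 245, exons overlapping Gm11670) and Nkd1 (503.6 ± 62.9 against 308 ± 51.9). The glycolysis genes were higher (7.88e-06, 0.406 with an estimated correlation), with 16 of 17 members above 0 and Ldha at 6719 ± 788 against 4211 ± 373. The endothelial markers were higher (0.00091, 0.406 with an estimated correlation), with 4 passing when adjusted over the list alone and Tek at log2 0.95. The transmitter and potassium uptake genes (0.0238, 0.559 with an estimated correlation), with the glutamate receptor gene Grm3 at 22960 ± 3210 against 15240 ± 2020, and the astrocyte markers (0.0393, 0.589 with an estimated correlation), with Slc1a3 at 163100 ± 5550 against 118200 ± 19400, were higher by small medians (0.171 and 0.17). The cholesterol synthesis genes were higher at the limit of the threshold (0.05, 0.579 with an estimated correlation, and 0.0596 with TMM scaling). The meningeal fibroblast markers were higher (0.031, 0.532 with an estimated correlation), and were not called with the replicate number as a block (0.0703). The mitochondrially encoded genes were lower (0.0136, 0.589 with an estimated correlation), with mt-Cytb at 168700 ± 20400 against 310300 ± 249000. Deep layer astrocyte replicate 2 stood apart with a mitochondrial share of 16.04% of reads. Without it and upper layer non-astrocyte replicate 1, the mitochondrial list pointed up (0.276) and the meningeal list was not called (0.115). No list of this comparison stayed called with an estimated correlation.

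Not called between the astrocyte layers were the Hedgehog response genes (adjusted p = 0.0624), of which Hhip fell, and the white matter and fibrous astrocyte genes (0.0964) and BMP response genes (0.168), of which Id1 fell. Nor were the oligodendrocyte precursor genes (0.0964), the neuron markers, the deep layer neuron genes, the immediate early and dissociation stress genes and the reactive astrocyte genes (0.129 each), the Notch genes (0.153), the cell cycle genes (0.243), the microglia markers (0.254), the interneuron markers (0.316), the mural cell markers (0.396), the upper layer neuron and axon guidance genes (0.485 each), the synapse-regulating factors (0.512), of which Chrdl1 rose, the blood genes (0.539), the neuroblast genes (0.647) or the ependymal markers (0.985). When adjusted over the list alone, 4 neuron markers were higher and 1 lower, and 3 upper layer neuron genes were higher. The median and mean differed in sign for the interneuron (-0.051 and 0.053) and BMP (-0.05 and 0.028) lists, and the ependymal list had a median of 0.003 with a test that pointed down.

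Between the astrocyte layers 18 of 22575 genes were called, 9 higher and 9 lower, 17 of them at least 2-fold, and 2334 had an unadjusted p under 0.05. Of the calls, 63.2% were higher with edgeR and DESeq2's size factors and 71.1% with DESeq2, against 9 of the 18 here. With the replicate number as a block shared by all fractions, 89 genes were called, 66 higher and 23 lower. The pairing of these libraries bears only on a block within fraction, which gave 188 calls, 127 higher and 61 lower. All 18 were among the calls of both. By limma, Ugt8a (adjusted p = 0.0376) and Lum (0.0374) were called with the shared block and not without a block. In bulk tissue 15 of the 18 genes differed in the same direction and 2 were called, an overlap that was not tested. In a fit of only these libraries 1 gene was called, Hhip (adjusted p = 0.0283), and Lef1 stood at 0.223, Id1 at 0.277 and Inka2, Eogt and Cntnap2 at 0.286. With all groups in the fit, these 6 genes stayed called whichever library was left out. Chrdl1 lost its call without upper layer replicate 3 (adjusted p = 0.0508). Tnfrsf19 did without deep layer replicate 1 (0.0603) and upper layer replicates 2 (0.115) and 3 (0.116), and Art3 without upper layer replicates 1 (0.0538), 2 (0.0613) and 3 (0.0606). Lyn did without upper layer replicates 1 (0.0706) and 3 (0.0871), Tspan2 without upper layer replicates 1 (0.0621) and 3 (0.0508), and Mbp without deep layer replicate 1 (0.0504) and upper layer replicates 1 (0.0676) and 2 (0.101). The count rose to 35 without deep layer replicate 1, 35 without replicate 2 and 56 without replicate 3. It was 21 without upper layer replicate 1 and 12 without upper layer replicate 2 or 3. The count of astrocyte-enriched genes, 5 in all, ran from 2 to 9 as single libraries were left out.

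Whether the layer difference in astrocytes differed from that in non-astrocytes was tested directly. Reln was the 1 gene called (log2 -2.19, SE 0.281, limma adjusted p = 0.0285), as it was higher in upper layer non-astrocytes while the astrocyte libraries held 87 to 109 in both layers. edgeR also called 1 gene, DESeq2 called 59, and 1350 genes had an unadjusted p under 0.05. Reln kept its call without deep layer astrocyte replicate 2 only, and lost it without any other single library of the astrocytes or non-astrocytes (adjusted p = 0.0514 to 0.194), and in a fit of only these groups (0.65). Chrdl1 (log2 0.36, adjusted p = 0.873) and Il33 (log2 -1.13, adjusted p = 0.726) did not pass. For Il33 the layer difference in astrocytes was itself not called (limma adjusted p = 0.339). For Chrdl1 the test cannot tell whether the difference is particular to astrocytes. Its level in non-astrocytes was 42.4-fold lower, between those of Aldh1l1 (31.5-fold) and Aldoc (57.7-fold). Astrocyte RNA left in that fraction would carry the same layer difference. The 17 cholesterol synthesis genes all had a higher upper minus deep difference in astrocytes than in non-astrocytes (camera adjusted p = 1.98e-14, 0.0834 with an estimated correlation), 7 when adjusted over the list alone, with Fdps at log2 1.26. The upper layer neuron genes had a lower one (2.17e-05, 0.0834 with an estimated correlation), 5 when adjusted over the list alone, with Unc5d at log2 -2.27. The neuron (0.00219) and interneuron (0.0175) markers were lower as well, and the glycolysis genes (0.000345), endothelial markers (0.0048), Wnt response genes (0.00747), astrocyte markers (0.0113) and myelin genes (0.0209) were higher. None of these list calls was kept with an estimated correlation, where the adjusted p ran from 0.0834 to 0.638. Without the libraries that stood apart, upper layer non-astrocyte replicate 1 and deep layer astrocyte replicate 2, the interneuron (0.177) and endothelial (0.105) lists were not called.

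Across the 22575 genes, the layer differences of the fractions were compared in a family of 3 correlations. Pearson's r was 0.125 between non-astrocytes and bulk tissue, 0.016 between astrocytes and bulk tissue and -0.014 between astrocytes and non-astrocytes. The last ran from -0.151 without upper layer non-astrocyte replicate 2 to 0.164 without upper layer non-astrocyte replicate 1. Over the 5608 genes with higher levels (log2 of the mean CPM of at least 5), the values were 0.347, 0.049 and 0.189. Genes are not independent replicates, so no p-value is given.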

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

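The tests of oligodendrocyte RNA carried into astrocyte libraries, of more RNA of every other cell type, of sequencing depth, of mitochondrial displacement and of other splits of the samples were chosen after the results they address were seen, while those of genomic DNA and of RNA of another cell type were set before theirs were seen.

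The oligodendrocyte and myelin genes were lower in upper than in deep layer astrocytes. Oligodendrocyte RNA carried into the sorted astrocytes may be part of this and stays open for the 13 members that were lower in astrocytes than in non-astrocytes (a median of 2.05% of that level), as over all 15 members the layer differences of astrocytes and non-astrocytes had an r of only 0.02. For Aspa and Gpr37 it is argued against, since both were higher in astrocytes than in non-astrocytes (log2 2.78 and 1.08). More RNA of every other cell type in the deep layer libraries is argued against by the endothelial markers, whose median went the other way (0.58). Myelin genes expressed at a low level by deep layer astrocytes stay open as an untested difference between layers.

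Upper layer non-astrocyte replicate 1 held a read in 30333 genes, far from the other libraries. Genomic DNA in this library is a candidate explanation, as 92.3% of 826 chemoreceptor genes, which are largely silent outside sensory organs, had a read, 3.28 times the share in the highest other library (28.1%). Deeper sequencing is argued against, since 6 libraries had more reads and this library held 3977 more genes than the highest of them (26356). The design gives no biological explanation for a single library, and none was tested.

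Deep layer astrocyte replicate 2 had a mitochondrial share of 16.04%. Mitochondrial reads that merely displaced the rest are argued against, since over 13554 nuclear genes its deviations from its group had an SD of 0.683, 1.59 times that of the highest other astrocyte library. RNA of another cell type is argued against as well, since the highest of 10 cell type lists lay only 0.29 (log2) above the other deep layer astrocyte libraries, and the microglia markers lay at -0.89. Damage to the cells or RNA during dissociation was not tested, and no biological explanation was tested.

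The layer difference differed between astrocytes and non-astrocytes, by a test of the difference itself, for Reln (-2.19, adjusted p = 0.0285) and for the lists that follow, each given as the median log2 layer difference in astrocytes minus that in non-astrocytes. The cholesterol synthesis genes stood at 0.867 (1.98e-14, and 0.0834 with an estimated correlation). The upper layer neuron genes stood at -0.469 (2.17e-05, and 0.0834), the neuron markers at -0.439 (0.00219, and 0.378) and the interneuron markers at -0.418 (0.0175, and 0.51). Above 0 were the endothelial markers at 0.7 (0.0048, and 0.51), the Wnt response genes at 0.623 (0.00747, and 0.336), the myelin genes at 0.528 (0.0209, and 0.546), the glycolysis genes at 0.409 (0.000345, and 0.51) and the astrocyte markers at 0.264 (0.0113, and 0.638). Their explanations were not weighed.

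For the astrocyte layers, the 10 splits of the 6 libraries are too few to give a share under 0.05. The real split alone, 1 of the 10, gave 18 genes and the highest other gave 10, and for astrocyte-enriched genes the real split gave 5 and the highest other 0. With a block within fraction, where the numbers pair the libraries, the real split gave 188 genes and the highest of the splits that part every pair gave 1, again with too few splits (4). For astrocytes against non-astrocytes, 1 of 100 splits drawn of 210, the real one, gave as many genes (14425 in a fit of these groups, and 1 in the highest other). Every other split mixes the fractions and so puts their large difference into the spread, which by itself keeps calls few. These splits therefore cannot exclude chance as the source of that count. The same limit holds for astrocytes against bulk tissue (1 of 100, 14726 genes, and 0 in the highest other).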

How the results depend on the processing

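The settings added after the results were seen were TMM scaling, pseudocounts, quality weights, the block within fraction and leaving out the 2 libraries that stood apart. Where a value changed, the cause was not tested, except that a fit of only the groups compared and a fit without a library have fewer libraries, and a fold threshold keeps fewer genes by construction. With 2 libraries on a side, leaving out 1 assumes that the lone library varies like the other groups. No setting varied the depth. The test on simulated counts recovered 52.2% of 2-fold changes between the astrocyte layers, among genes with a mean value of at least 100.

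For astrocyte layers, non-astrocyte layers, bulk layers and the difference of layer differences in turn, the counts of genes were 142, 139, 428 and 59 with DESeq2, 1, 0, 1093 and 0 with only the groups compared, 89, 3, 168 and 3 with the replicate block, 188, 33, 261 and 4 with the block within fraction, and 46, 4, 277 and 2 without the 2 libraries. With limma over only the groups compared, 2114 astrocyte genes, 655 non-astrocyte genes and 932 genes for the difference of layer differences had an unadjusted p under 0.05. Quality weights gave 110 for astrocytes, 710 for bulk tissue and 2 for the difference. edgeR gave 7 for non-astrocytes and 170 for bulk tissue, and 8 and 164 with DESeq2's size factors. With a pseudocount of 10 the counts were 4 and 340, and without a filter 13 for non-astrocytes. For astrocyte-enriched genes the counts were 50 with DESeq2, 8 with edgeR and DESeq2's size factors, 41 with quality weights, 0 with only the groups compared, 9 with a pseudocount of 10, 25 and 54 with the blocks, 16 without the 2 libraries and 8 when enriched over bulk tissue. At least 2-fold changes numbered 9960 against non-astrocytes and 9691 against bulk tissue. With single libraries left out, the counts ran from 12 to 56 for astrocytes, 2 to 9 for astrocyte-enriched genes, 0 to 5 for non-astrocytes, 11 to 20 for bulk tissue and 0 to 2 for the difference.

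The correlation between astrocytes and non-astrocytes was 0.159 without the 2 libraries and 0.189 over genes with a log2 of the mean CPM of at least 5. It ran from -0.151 to 0.164 with single libraries left out. That between non-astrocytes and bulk tissue was 0.075 with edgeR, 0.069 without a filter, 0.109 by Spearman, 0.108 without the 2 libraries and 0.347 over the higher genes, and ran from 0.082 to 0.121. That between astrocytes and bulk tissue was -0.011 by Spearman and 0.049 over the higher genes, and ran from -0.016 to 0.043.

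Of the named genes' values under all alternatives, 6597 kept their direction and side of the threshold, 82 became called, 95 lost a call and 10 changed sign. With single libraries left out, Aldh1l1 between non-astrocyte layers ran from -0.196 (without deep layer replicate 1) to 0.288, and was -0.04 without upper layer replicate 2. C1ql1 there ran from -1.458 to 0.122 and mt-Co1 from -1.468 to 0.006, both highest without upper layer replicate 1. Between astrocyte layers mt-Cytb ran from -0.939 to 0.014 and mt-Nd2 from -1.219 to 0.022, both highest without deep layer replicate 2, and for these 4 genes the highest value was also that without the 2 libraries. Of the lists, 325 values kept both, 94 lost a call and 1 changed sign, the mitochondrially encoded genes between astrocyte layers (0.276 without the 2 libraries). Of the lost calls, 58 arose with an estimated correlation, 25 with fry, which tests a list against no change, and 8 without the 2 libraries.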

Other observations

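The test of shared animals among bulk libraries was chosen after the result was seen, while that of astrocyte transcripts in undissociated tissue was planned.

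If layer differences of astrocyte genes were present in the tissue before dissociation, bulk tissue would show them. Over 456 genes at least 4-fold higher in astrocytes than in both non-astrocytes and bulk tissue, the layer differences of astrocytes and bulk tissue had a Pearson r of 0.2 and a Spearman correlation of 0.21, and 56.4% had the same direction. All 5 called astrocyte-enriched genes had the same direction in bulk tissue, but these were not required to be 4-fold higher in astrocytes. Inka2 stood lower in deep layer astrocytes (1315, 1091 and 1529) than in deep layer bulk tissue (2904 and 2887). Its layer difference in bulk tissue therefore cannot be assigned to astrocytes. Of the 456 genes, 9 were called with a block within fraction, and 6 of these had the same direction. The correlation over the 456 genes goes with a part of the astrocyte layer differences being present before dissociation, but it was weak.

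Y-linked genes were lower in replicate 1 than in replicate 2 of bulk tissue in both layers. Kdm5d stood at 0 and 0 in replicate 1 against 321 and 342 in replicate 2 of the deep and upper layers, and Ddx3y at 5 and 5 against 317 and 329, while Uty kept 157 and 134 against 413 and 399. Xist, a transcript of the inactive X chromosome, went the other way, at 39717 and 44916 against 18110 and 22274. The sex make-up of the animals thus differed between replicates 1 and 2. Bulk replicate 2 of both layers held Xist beside Kdm5d, and so RNA of both sexes. The same was true of every sorted library, with Xist from 36833 to 135481 and Kdm5d from 476 to 949. Upper and deep bulk libraries with the same number may come from the same animals, but separate animals of the same sex make-up would give this pattern too. Across 13037 autosomal genes, the deviations of libraries with the same number had an r of 0.15. With only 2 replicates per layer the other pairing is its mirror (-0.15), so the number of pairs limits this test.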
